A study of Mus musculus with 2 samples.

How the data were processed

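Total RNA-seq libraries were made from pools of 100 granulocyte-monocyte progenitors of male C57BL/6J mice with added spike-ins, per the labels. The series holds 1 group of 2 libraries, numbered by the biological replicate number in the labels. Both libraries carry the same donor identifier and separate sample identifiers, and the labels do not say whether they are separate animals.

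Each library has a deposited gene table of 69691 rows and a deposited transcript table of 129984 rows. The expected counts are estimated read counts that need not be whole, as the authors deposited them. The deposited TPM values are scaled to a fixed total over all rows, spike-ins and mitochondrial genes included. The deposited FPKM values are scaled by effective length and by library size. The percent values in the deposited transcript tables give the share of a gene's TPM on each transcript. Values were made from reads aligned to the transcriptome on mm10 with annotation M4, per the text files deposited with each library. The aligner and the quantification tool are not given in the sources used here, nor is it stated whether counting used strand, so genes with an overlapping or antisense partner are uncertain.

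The gene tables hold 43346 Ensembl rows, 26248 rows with numeric identifiers and 97 spike-in rows. Symbols, biotypes and gene spans came from GENCODE M21, on the same assembly and later than M4, by Ensembl identifier without version, and 42462 rows matched. The 884 unmatched rows and the numeric rows entered no list. The correlations not limited to protein-coding genes, the chi-square and the count of ratios over 4-fold drew on all rows that met their cut, spike-ins included, and the edgeR spread on all Ensembl rows. Of 249 genes in 21 lists, the RNA Snhg1 had no matching row. Copies of near-identical sequence share reads, and values of multigene families are uncertain for that reason.

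A mean over the 2 libraries is given with its SD, except list medians and shares of TPM. Log values are log2(TPM + 1), which understates ratios of low genes. Shares of counts have 95% Wilson intervals, and a count of 0 allows up to 3 counts, equal to 0.0741 CPM (counts scaled to the library total) in replicate 1 and 0.0841 in replicate 2. The labels name no molecular identifiers, so intervals on shares of counts and floors cover counting error only.

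The lists and the 11 contrasts between them were fixed before the data were examined. A contrast is the difference in mean log2(mean TPM + 1), with a two-sided permutation test across genes of 100000 resamples, or an exact permutation test where a list had fewer than 10 genes, adjusted by Benjamini-Hochberg over the 11. The level of a list is the percentile of its median among 10000 random protein-coding lists of its size. The replicate ratio of a list is the median log2 ratio of its protein-coding members of 1 TPM or more, set against 10000 lists drawn for each member from the 200 genes nearest in mean TPM, and was chosen after seeing the data. Replicate spread came from edgeR 4.0.16 in R 4.3.3 on expected counts rounded to whole numbers, with TMM factors, 10 counts in at least 1 library and an intercept alone, which leaves 1 residual degree of freedom, and no gene was tested. DESeq2 1.42.0 was an alternative. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, and sequences were compared with BLAST 2.17.0.

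Steps were tested on simulated data. Among 43346 Ensembl rows, 200 genes were changed 4-fold, all drawn from rows of 100 counts or more on average. Of these, 93.5% were over 2-fold in the right direction. Lists of changed genes were called in 100% of draws and lists of unchanged genes, also of 100 counts or more, in 6%. Genes were simulated as independent, so these rates need not hold for lists of low or co-varying genes. A simulated coefficient of variation of 0.3 came back as 0.324 over 10236 rows, the changed ones included. List contrasts without a shift were called in 6% of draws and with a shift of 4 log2 units in 100%.

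Named genes follow a rule fixed before the data were examined. It takes the 4 highest members of each list, all sort, gate and sex genes, the 20 highest protein-coding genes, the 10 genes furthest apart between replicates at 10 TPM or more, the 5 highest non-coding RNAs, and for transcripts the 5 highest genes and the 5 largest changes of share. Other genes were named after their values were seen, as examples of a count or of 0 counts, and all genes of the closing section outside the lists. Some genes that the rule takes are not reported here. The alternatives were other pseudocounts, units, filters, scalings and normalizations, and each replicate left out in turn.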

Results

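Total RNA was sequenced from granulocyte-monocyte progenitors, the bone marrow cells that give rise to neutrophils and monocytes, taken from male C57BL/6J mice of 5 to 6 weeks. There was 1 group of 2 libraries, each made from a pool of 100 cells and called replicate 1 and replicate 2 after the labels. Replicate 1 held 40509954 expected counts and replicate 2 held 35675702. With no second group, the data describe the expressed genes of this population, the order of fixed gene lists within it, and the spread between the libraries. The labels give separate samples but do not say whether these came from separate animals, so every SD below measures only the spread between these 2 libraries, which may be technical. Gene spans are those of GENCODE M21 on GRCm38.

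Genes of the surface proteins commonly used to sort this population were expressed as follows. Fcgr3, an Fc gamma receptor, stood at 140 ± 11.5 TPM (SD, n = 2), Cd34 at 109 ± 2.79 TPM and Kit, the stem cell factor receptor, at 62.7 ± 9.23 TPM. Fcgr2b was at 52.9 ± 3.56 TPM, Cd48 at 83.1 ± 4.37 TPM and Ptprc, which encodes CD45, at 56.5 ± 2.22 TPM. Ly6a, which encodes the stem cell antigen Sca-1, and Il7r, the interleukin 7 receptor of lymphoid progenitors, had 0 counts in both libraries, which allows up to 0.0741 CPM in replicate 1 and 0.0841 in replicate 2. Slamf1 had 1 count in each library. Flt3, a receptor of earlier progenitors, was at 2.31 TPM in replicate 1 and 5.95 TPM in replicate 2. The Y-linked genes Eif2s3y (39.1 ± 6.20 TPM), Ddx3y (18.9 ± 1.32 TPM), Uty (13.8 ± 1.13 TPM) and Kdm5d (11.2 ± 4.11 TPM) were detected in both libraries and Xist had 0 counts.

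Primary (azurophil) granule genes were among the most abundant transcripts of the cells. All 12 members of that list reached 1 TPM in both libraries. Mpo, myeloperoxidase (chromosome 11, 87793581 to 87804413), stood at 6467 ± 191 TPM (SD, n = 2), and Elane, neutrophil elastase (chromosome 10, 79886247 to 79888215), at 3062 ± 112 TPM. Prtn3, proteinase 3, was at 1447 ± 524 TPM and Srgn, the serglycin proteoglycan of granules, at 1090 ± 169 TPM. Members of the list for the later specific and gelatinase granules were mostly far lower, and 5 of 13 reached 1 TPM in both libraries. That list is not limited to proteins stored in those granules. Its highest members were S100a8 at 341 ± 152 TPM and S100a9 at 111 ± 68.6 TPM, which encode the calprotectin subunits. They were followed by Ngp at 22.8 ± 31.0 TPM and Lcn2, lipocalin 2, at 18.1 ± 8.75 TPM. Mmp25 and Orm1 had 0 counts in both libraries.

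The mean of log2(mean TPM + 1) was 8.59 for the azurophil list and 2.94 for the specific and gelatinase list, a difference of 5.65. It was 5.27 in replicate 1 and 6.79 in replicate 2. A two-sided permutation test across genes gave p = 6.0e-05, adjusted p = 8.25e-05 by Benjamini-Hochberg over the 11 contrasts fixed before the data were examined. Genes are not independent replicates, and no test across the 2 libraries was run.

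**Figure D1:**
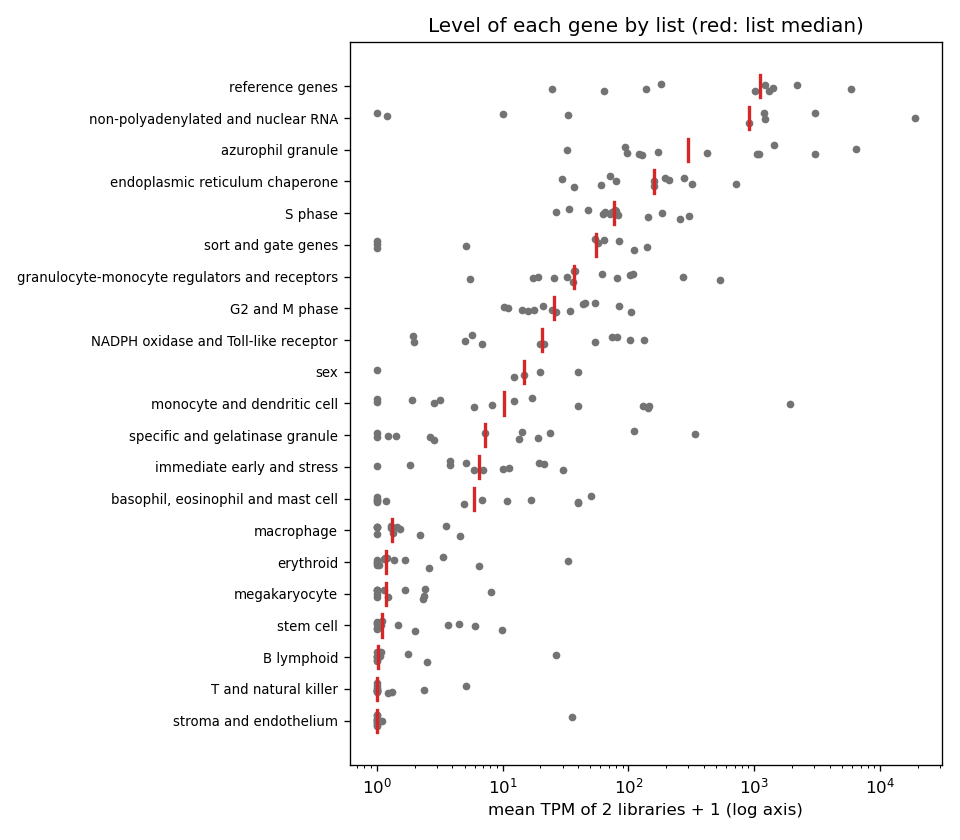
Each point is a gene of 1 of the 21 fixed lists, placed by its mean TPM over the 2 libraries plus 1 on a log axis, and red lines mark list medians. The azurophil median is 296 TPM, against 6.24 TPM for specific and gelatinase granules (12.4 in replicate 1, 0.210 in replicate 2) and 0 TPM for the T and natural killer list.

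Regulators and cytokine receptors of the granulocyte-monocyte lineage were all expressed, with 14 of 14 at 1 TPM or more in both libraries. Ms4a3, a membrane protein typical of these progenitors, stood at 531 ± 16.1 TPM (SD, n = 2), Myb at 272 ± 3.05 TPM, Spi1 (PU.1) at 109 ± 12.5 TPM and Irf8 at 103 ± 0.820 TPM. Cebpa was at 35.7 ± 0.622 TPM, Gfi1 at 24.7 ± 6.33 TPM, and the receptors Csf3r and Csf1r at 60.5 ± 10.6 and 35.3 ± 2.29 TPM.

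Genes typical of other lineages were mostly near 0. Of the erythroid list 4 of 14 reached 1 TPM on average: the transferrin receptor Tfrc at 32.0 ± 0.955 TPM, Car2 at 5.52 ± 1.00 TPM, Car1 at 2.34 ± 0.389 TPM and Gata1 at 1.59 ± 0.735 TPM. Among the 12 megakaryocyte genes 4 did: Itga2b at 7.08 ± 1.52 TPM, Selp at 1.43 ± 0.509 TPM, Itgb3 at 1.39 ± 0.693 TPM and Vwf at 1.33 ± 1.58 TPM. The B lymphoid list had 2 of 12, Cd79b at 25.6 ± 0.276 TPM and Igll1 at 1.52 ± 0.877 TPM, followed by Rag2 at 0.130 and 1.39 TPM and Blnk at 0.150 and 0 TPM in replicates 1 and 2. The T and natural killer list also had 2 of 12, Gata3 and Lck. Gata3 was at 0 and 8.18 TPM in replicates 1 and 2, from only 0 and 22 counts. Lck was at 2.65 and 0.0700 TPM, from 118 and 3 counts. They were followed by Tcf7 at 0.650 and 0 TPM and Cd4 at 0.0100 and 0.440 TPM. Stem cell genes were led by Meis1 at 8.88 ± 3.96 TPM, Hlf at 5.07 ± 0.311 TPM, Mllt3 at 3.47 ± 0.877 TPM and Tie1 at 2.67 ± 1.12 TPM, and 5 of 13 reached 1 TPM on average. Macrophage genes were led by Adgre1 (F4/80) at 3.59 ± 0.672 TPM, Vcam1 at 2.54 ± 0.764 TPM, Axl at 1.19 ± 1.00 TPM and Mrc1 at 0.540 ± 0.170 TPM. Of the stroma and endothelium list only Pecam1 reached 1 TPM, at 34.7 ± 2.04 TPM, while Cdh5 was at 0 and 0.200 TPM in replicates 1 and 2 and the other 10 members, collagens included, had 0 counts in both libraries.

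The regulator and receptor list lay above each of these lists. Its mean log2(mean TPM + 1) of 5.65 exceeded the erythroid list by 4.73, the stem cell list by 4.75, the megakaryocyte list by 4.98, the macrophage list by 5.02, the B lymphoid list by 5.05, the stroma and endothelium list by 5.21 and the T and natural killer list by 5.29. Each of these 7 gave a permutation p of 2.0e-05, the smallest that 100000 resamples can give two-sided, with adjusted p = 3.14e-05, and each difference had the same sign in both libraries. The direction was foreseeable from the choice of lists, so these p-values describe the lists and are not independent evidence of cell identity. With members of 1 TPM or more alone, the B lymphoid list kept 2 genes and the difference of 2.62 did not pass (adjusted p = 0.0926, exact permutation test).

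Genes of basophils, eosinophils and mast cells were partly expressed, with 7 of 12 at 1 TPM or more on average. Mcpt8, a basophil protease, was at 49.1 ± 15.0 TPM (SD, n = 2), Hdc, the histamine-forming enzyme, at 38.8 ± 1.24 TPM, Cpa3 at 38.7 ± 4.01 TPM and Ms4a2, the beta chain of the IgE receptor, at 15.7 ± 7.69 TPM. Of the eosinophil genes, Prg3 was at 8.12 and 3.68 TPM in replicates 1 and 2, Epx had 29 counts in replicate 1 alone, and Prg2 and Il5ra had 0 counts in both libraries, as did the mast cell genes Tpsb2 and Cma1. The regulator list lay 3.22 above this list (permutation test, p = 0.00056, adjusted p = 0.000616). With members of 1 TPM or more alone the difference was 1.53 and did not pass (adjusted p = 0.0577, exact permutation test).

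Of the monocyte and dendritic cell genes, 11 of 14 were at 1 TPM or more on average and 10 of 14 in both libraries. Ly6c2, a monocyte surface antigen, stood at 1918 ± 154 TPM (SD, n = 2), F13a1 at 144 ± 6.40 TPM, Zeb2 at 142 ± 0.0283 TPM and Ms4a6c at 130 ± 0.509 TPM. Siglech of plasmacytoid dendritic cells had 0 counts in both libraries, and Xcr1 had 0 and 2 counts in replicates 1 and 2. In the same order Cd74 was at 1.80 and 0 TPM, H2-Aa at 3.27 and 1.14 TPM and H2-Ab1 at 15.3 and 7.41 TPM. The regulator list lay 1.72 above this list, which did not pass the threshold (permutation test, p = 0.0898, adjusted p = 0.0898). On CPM, which is not divided by length, the difference was 2.37 and passed (adjusted p = 0.0260, permutation test).

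Cell cycle genes were expressed throughout, with 14 of 14 S phase genes and 14 of 14 G2 and M phase genes at 1 TPM or more in both libraries. Pcna, the replication clamp, was at 304 ± 4.67 TPM (SD, n = 2), and the helicase subunits Mcm3, Mcm6 and Mcm7 at 256 ± 22.5, 183 ± 3.75 and 143 ± 6.94 TPM. Top2a was at 104 ± 1.85 TPM, Mki67 at 84.0 ± 15.6 TPM, Birc5 at 53.2 ± 11.4 TPM and Aurkb at 44.4 ± 8.23 TPM. S phase genes lay 1.58 above G2 and M phase genes on the log2 scale (permutation test, p = 0.0004, adjusted p = 0.000489). The difference was 1.39 in replicate 1 and 1.84 in replicate 2. The lists hold different genes, so it does not show how many cells were in each phase.

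Endoplasmic reticulum chaperones, which fold secreted and granule proteins, were abundant, with 12 of 12 at 1 TPM or more in both libraries. Calr stood at 714 ± 102 TPM (SD, n = 2), Hsp90b1 at 320 ± 13.1 TPM, Hspa5 (BiP) at 276 ± 12.6 TPM and Manf at 209 ± 28.3 TPM. NADPH oxidase genes were expressed, with Rac2 at 132 ± 0.912 TPM, Cyba at 102 ± 24.8 TPM, Ncf1 at 79.8 ± 2.57 TPM and Ncf4 at 72.9 ± 17.4 TPM, while Toll-like receptor genes were lower, Tlr2 at 5.90 ± 0.742 TPM. Immediate early genes were modest, led by Zfp36 at 29.0 ± 6.40 TPM, Fos at 20.5 ± 5.28 TPM, Ier2 at 18.6 ± 3.72 TPM and Jun at 10.3 ± 3.15 TPM. The reference genes Eef1a1, Ppia, Gapdh and Actb were at 5835 ± 377, 2179 ± 137, 1418 ± 66.9 and 1313 ± 119 TPM.

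Against 10000 random lists of the same size drawn from protein-coding genes, 9 of the 21 lists had a median above the central 95%, and 0 lay below it. The 9 included the sort and gate, azurophil, regulator and receptor, S phase, and G2 and M phase lists. The rest were the NADPH oxidase and Toll-like receptor, chaperone, reference, and non-polyadenylated and nuclear RNA lists. The last holds non-coding RNAs set against protein-coding genes, and its median, 907 TPM, is the value of Gas5. A median of 0 TPM, the lowest possible, still lay at percentile 10.35 for T and natural killer genes and 10.7 for stroma and endothelium genes. The count of 0 lists below therefore says little. Against random lists of genes at 1 TPM or more, the G2 and M phase list fell to percentile 95.2 and the NADPH oxidase and Toll-like receptor list to 82.9, inside the central 95%. In that setting 9 lists lay below the central 95%: the erythroid, megakaryocyte, B lymphoid, T and natural killer, stem cell, macrophage, stroma and endothelium, basophil, eosinophil and mast cell, and immediate early lists. List members under 1 TPM were kept, so any list with a median under 1 TPM fell below this pool by construction. The specific and gelatinase list lay at percentile 87.7, at 97.8 without replicate 2, which is above the central 95%, at 43.8 without replicate 1 and at 3.62 against genes of 1 TPM or more. The monocyte and dendritic cell list lay at percentile 95.5, at 97.52 without replicate 2 and at 17.0 against genes of 1 TPM or more. The basophil, eosinophil and mast cell list lay at 83.0, and at 0.830 against genes of 1 TPM or more.

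A nuclear locus annotated as a long non-coding RNA, Gm42418 (chromosome 17, 39846958 to 39848788), took the largest share of each library, 31.5% of expected counts in replicate 1 (95% Wilson interval 31.49 to 31.52) and 29.4% in replicate 2 (29.40 to 29.43). RefSeq lists Gm42418 as a synonym of the 18S ribosomal RNA-related sequence Rn18s-rs5, and 1245 bases of it, 68.0%, lie within that gene. Mitochondrial ribosomal RNA took 13.6 ± 0.807% (SD, n = 2), ribosomal protein genes 4.61 ± 0.242% and mitochondrial protein-coding genes 1.55 ± 0.0691%. The last share leaves out counts given to nuclear copies of mitochondrial genes. For the copy Gm28437 these differed widely between the libraries, so the share and its spread are uncertain. As shares of TPM, ribosomal protein genes held 12.1% and mitochondrial protein-coding genes 2.82%. Together Gm42418, its neighbour Gm26917 and mitochondrial ribosomal RNA held 44.5 ± 0.473%. Mpo alone held 0.888 ± 0.0643%. Lars2, which encodes mitochondrial leucyl-tRNA synthetase, took 3.11% in replicate 1 and 1.27% in replicate 2, and 0.808% of TPM on average. The intervals cover counting error only.

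**Figure D2:**
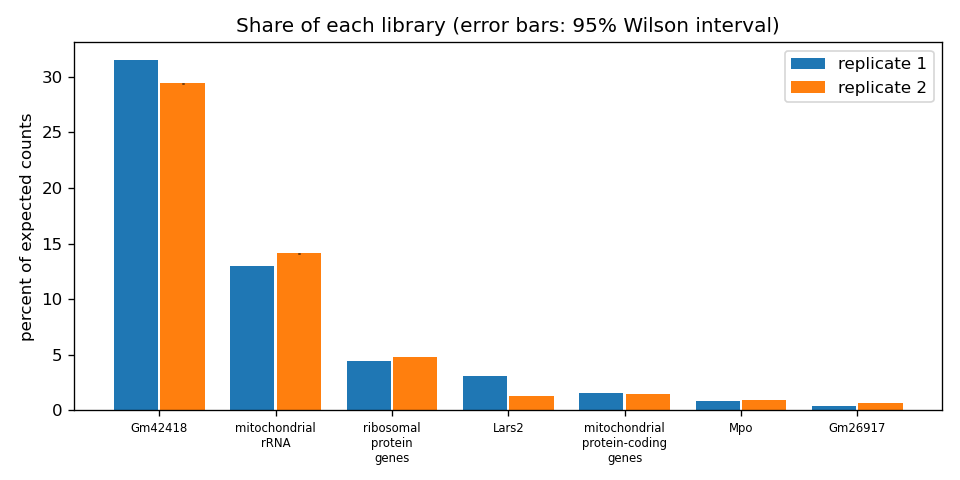
Bars show the percent of each library's expected counts on 7 genes or gene classes in replicates 1 and 2, with 95% Wilson intervals too narrow to see. Gm42418 holds 31.5% and 29.4%, and Lars2 3.11% and 1.27%.

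Among non-coding RNAs, Gm42418 stood at 249635 ± 14769 TPM (SD, n = 2), Rn7sk, the 7SK small nuclear RNA, at 18996 ± 2268 TPM, Mir6236 at 8318 ± 514 TPM, Rpph1, the RNA of ribonuclease P, at 3056 ± 2481 TPM and Gm26917 at 2270 ± 853 TPM. Mir6236 has an effective length of 8.30 bases, so its TPM rests on 1939 and 2034 counts. Rmrp was at 1216 ± 353 TPM and Malat1 at 1192 ± 50.6 TPM. The 20 protein-coding genes of highest mean TPM were led on average by Lars2 at 8083 ± 4865 TPM, though in replicate 2 Lars2, at 4643 TPM, lay below Mpo, mt-Atp8, Eef1a1 and mt-Co1. An alternative rescaling of TPM left out Lars2 together with Gm42418, Gm26917 and Mir6236. Whether the reads on Lars2 came from its message was not tested. The 20 genes also held Mpo, Elane, Eef1a1 and Plac8, the last at 2633 ± 312 TPM. The 20 also held mt-Atp8, mt-Co1, mt-Atp6 and mt-Cytb of the mitochondrion and the ribosomal protein genes Rps12, Rpl41, Rpl10, Rpl23a, Rps24, Rpl26, Rpl32, Rps18, Rps27 and Rps27a, which ranged from Rps12 at 4585 ± 116 TPM down to Rps27a at 2299 ± 238 TPM. Mitochondrial genes with a nuclear copy, mt-Co3 and mt-Co2 among them, may rank too low here.

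The libraries shared 9782 protein-coding genes at 1 TPM or more out of 21474, with 377 more in replicate 1 alone and 455 in replicate 2 alone. Across all 11672 table rows of 1 TPM or more on average, spike-ins and unmatched rows included, Pearson's r of log2(TPM + 1) was 0.915 and Spearman's rho 0.918. For the 10278 protein-coding genes among them r was 0.947 and rho 0.944. These are correlations across genes, which are not independent replicates. Of 6095 protein-coding genes at 10 TPM or more, 5904, or 96.9%, lay within 2-fold between the libraries. The counts differed by more than counting noise, with a chi-square of 72.7 per degree of freedom over 13247 rows. Rows of large counts that differ, such as Lars2, weigh heavily in this sum, and shifts between identical copies raise it. It therefore does not describe the typical row. The counts differ, so the tables are not 1 table deposited again. This does not tell separate animals from separate amplifications. The biological coefficient of variation from edgeR was 0.593 over 13930 Ensembl rows, 0.252 over the 10266 of 100 counts or more on average. Along edgeR's trend it was 1.49 below 1 log2 CPM and 0.139 above 5 log2 CPM.

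The 10 genes furthest apart between the libraries at 10 TPM or more were short RNAs and pseudogenes with 0 counts in 1 library. Gm26377, Gm23123, Gm26497, Mir1949 and Mir719 had counts in replicate 1 alone, from 14.4 for Mir719 to 83.5 for Gm23123. Gm27505, Snora43, Gm22270, Gm16550 and Gm28911 had counts in replicate 2 alone, from 17.5 for Gm28911 to 36.0 for Gm22270. Their effective lengths ran from 3.64 bases for Gm26497 to 17.3 for Gm23123.

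Of the members of the specific and gelatinase list at 1 TPM or more on average, 8 of 9 were higher in replicate 1. Ngp was at 44.7 TPM in replicate 1 and 0.880 in replicate 2, from 1310 and 23 counts, Chil3 at 24.7 and 0.190 TPM, Camp at 24.4 and 1.99 TPM, and S100a8 at 448 and 233 TPM. Of the G2 and M phase genes 11 of 14 were higher in replicate 1, with Ube2c at 36.0 and 11.8 TPM, and of the basophil, eosinophil and mast cell genes 5 of 7, with the IgE receptor gene Fcer1a at 7.91 and 0.0600 TPM. The median log2 ratio of replicate 2 to replicate 1 was -2.22 for the specific and gelatinase list, -0.62 for the basophil, eosinophil and mast cell list and -0.37 for the G2 and M phase list. The first was -3.55 with pseudocount 0.1 and the second -0.39 with TMM factors. The 3 lists were at percentiles 0, 0.05 and 0.03 of 10000 protein-coding lists matched on mean expression. The azurophil list was at percentile 0.330, with a median of -0.19. The S phase list was at percentile 58.9 and the regulator and receptor list at 72.5. Percentiles describe these 2 libraries and are not tests of a condition.

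**Figure D3:**
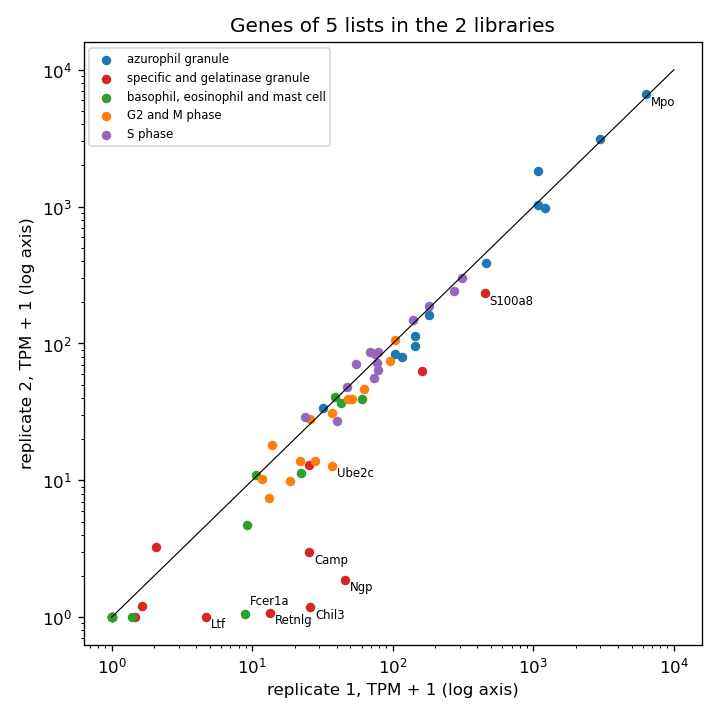
Genes of 5 lists are placed by TPM plus 1 in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, with a line of equal values. Ngp, Chil3, Camp, Retnlg, Ltf and Fcer1a lie far below the line, while Mpo lies on it at 6332 and 6602 TPM.

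The most abundant transcript was the same in both libraries for 75 of 82 list genes with more than 1 annotated transcript and 10 TPM in both, which is 91.5% (95% Wilson interval 83.4 to 95.8). For Mpo it held 64.6% of the gene's TPM in replicate 1 and 76.7% in replicate 2, for Eef1a1 82.9% and 78.4%, for Ppia 84.6% and 85.8% and for Ly6c2 85.2% and 85.4%. Prtn3 changed its leading transcript, whose share was 68.9% in replicate 1 and 45.8% in replicate 2. Large differences in a transcript's share were found in Tpx2 (0% and 32.9%), Aurkb (60.4% and 27.6%), Uty (0% and 28.1%) and Kit (59.4% and 86.1%). These differences have no test. The interval on the 82 genes treats chosen genes as independent draws, so it describes neither counting error nor replicate spread.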

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

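The rows below entered no list and no contrast between lists, though they were among the rows of the correlation between libraries, and each kind held, in at least 1 library, more counts than the 3 that a count of 0 allows. Ensembl rows with no match in M21 held 51243 counts in replicate 1 and 48089 in replicate 2, or 0.126% and 0.135% of each library, and 83 of the 884 reached 1 TPM on average. Rows with a numeric identifier held 0 counts in replicate 1 and 17 in replicate 2, on 2 rows. The spike-ins held 4831 and 2740 counts, with 16 and 19 of 97 detected and 15 in both.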

How the results depend on the processing

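The alternatives kept the direction of every list contrast, and 10 of 11 contrasts passed the threshold under each setting except 2: 11 on CPM and 7 with members of 1 TPM or more alone, where the stroma and endothelium list kept too few genes to test. On CPM the regulator list passed against monocyte and dendritic cell genes at 2.37. With members of 1 TPM or more it no longer passed against B lymphoid genes at 2.62, or basophil, eosinophil and mast cell genes at 1.53, where fewer genes were tested. Leaving out each replicate gave 10159 to 10237 detected genes, 44.2 to 44.9% for Gm42418, Gm26917 and mitochondrial ribosomal RNA together, and 9 to 11 lists above the central 95%. As a share of TPM those RNAs held 42.0%, ribosomal protein genes 12.1% against 4.61% of counts, mitochondrial protein-coding genes 2.82% against 1.55%, Lars2 0.808% against 2.19% and Mpo 0.647% against 0.888%. With random lists drawn from genes of 1 TPM or more, 9 lists lay below the central 95% and 7 above, since near-silent genes then leave the pool. Pearson's r was 0.837 with pseudocount 0.1, 0.978 with no filter, 0.896 at 10 TPM or more and 0.935 on posterior mean TPM, and rho was 0.873 and 0.926 under the last 2. The coefficient of variation was 0.593 with RLE factors, 0.613 with no filter, 0.252 at 100 counts or more and 0.322 with DESeq2. The cause of the other shifts was not tested. Chosen after seeing the data, rows over 4-fold between replicates at 10 TPM or more fell from 79 to 29 at an effective length of 50 bases or more and to 20 among protein-coding genes. The median log2 ratio of protein-coding genes was 0.04 in TPM and 0.00091 with TMM factors. Late granule, basophil, azurophil and G2 and M phase lists stayed outside the central 95% of matched lists under the 3 settings tried, while the stem cell list, at percentile 2.17, moved to 12.2 with TMM factors and to 15.0 with the 4 members of 100 counts or more. The immediate early list moved from 96.8 to 97.6 with TMM factors.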

Other observations

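The tests in this part were chosen after the replicate differences were seen, and the 2 outside marker lists were written before their values were looked at. Of 10 immunoglobulin constant genes, 1 reached 1 TPM and 8 had 0 counts in both libraries. Ighm, the mu heavy chain constant gene, stood at 135 ± 10.4 TPM (SD, n = 2), while Ighd was at 0.820 ± 0.156 TPM, Igkc had 0 counts and the 213 variable genes held 1 count in replicate 1 and 0 in replicate 2. Cd79b was at 25.6 ± 0.276 TPM with its partner Cd79a at 0 counts in both libraries.

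Of the 11 Hoxa genes 4 reached 1 TPM on average, led by Hoxa7 at 11.1 ± 0.290 TPM (SD, n = 2) and Hoxa9 at 5.67 ± 1.99 TPM, as did 2 of the 10 Hoxb genes, Hoxb3 at 3.74 and 0.720 TPM in replicates 1 and 2 and Hoxb4 at 1.26 and 1.84 TPM. None of the 18 Hoxc and Hoxd genes did. Replication-dependent histone genes, whose messages lack a poly(A) tail, were detected, with 48 of 63 at 1 TPM or more in both libraries. Their summed level was 2115 TPM in replicate 1 and 3322 TPM in replicate 2. Of the 8 protein-coding genes over 4-fold higher in replicate 2 at 10 TPM or more, 5 were histone genes: Hist1h2ao, Hist1h2ak, Hist1h4a, Hist1h4c and Hist1h4h. Of the 5 highest, Hist1h4d (227 and 555 TPM in replicates 1 and 2), Hist1h1e (155 and 286) and Hist1h2bg (115 and 193) were higher in replicate 2. Hist1h1b (157 and 134 TPM) and Hist1h2bl (158 and 114) were higher in replicate 1, though near-identical copies make single members uncertain. Prss34, a basophil protease gene, was at 44.7 TPM in replicate 1 and 1.15 in replicate 2.

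Members of the specific and gelatinase list were mostly higher in replicate 1, with a list median log2 ratio of -2.22. The median was at percentile 0 of matched lists, which restates the difference that drew attention to the list. Matched lists draw genes independently, so they do not cover genes that vary together. Read counting noise alone is argued against for Ngp, at 1310 and 23 counts in replicates 1 and 2, and Chil3, at 1002 and 7. Mmp8 was the 1 member of 9 that was higher in replicate 2. Noise from sampling few cells or molecules was not tested. Mature neutrophils in the replicate 1 pool may contribute: 7 outside markers had a median of -0.36, at percentile 2.23. But this moved to 30.5 with TMM factors and 3.47 with pseudocount 0.1, and 5 others, Il1b and Fpr1 included, had 0 counts in both libraries. Myelocyte-stage cells could also contribute: 7 of 9 outside markers reached 1 TPM on average and were at percentile 7.48. Of these 6 were higher in replicate 1, Fcnb among them, and Aldh2 was higher in replicate 2. Yet all 7 exceeded 10 TPM in replicate 2, so a small share would be hidden. Of the others Itgb2l was at 1.32 and 0.280 TPM and Ceacam10 had 0 counts. Among members of the 2 marker lists that were also in a fixed list, Cebpe (11.1 and 22.1 TPM), Csf3r (53.0 and 68.0) and Mmp8 (1.07 and 2.24) were higher in replicate 2. The rest, Ltf, Ngp, Camp, Chil3, Lcn2, Retnlg and Mmp9, were higher in replicate 1 and belong to the pattern itself. Both kinds of cell stay open as explanations, mature neutrophils because the call depends on the scaling. Any sort on Kit would be meant to remove such cells.

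The mitochondrial gene mt-Co3 had 58475 counts in replicate 1 and 7604 in replicate 2, while Gm28437 (chromosome 1, 24613189 to 24613971), identical to it over 783 bases, had 526 and 41752. The log2 ratio of their summed counts, replicate 2 over replicate 1 and scaled to the library totals, was -0.074. It was 0.08 ± 0.09 (SD) for 8 mitochondrial genes not paired with a copy here. The log2 ratio of mt-Co3 alone was -2.76, and a drop of that size in the mitochondrial transcript is argued against by the sum. The sum lay -1.75 SD from those genes, inside a bound of 2 SD set after the values were seen. A small decrease therefore cannot be excluded. Reads shared between the gene and its copy are a candidate explanation.

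Rows over 4-fold between replicates at 10 TPM or more may owe their ratios to short effective length. An effective length under 50 bases was found for 50 of 79 such rows, 63.3%, against 55 of the other 6397, 0.860%. Rows this short reach 10 TPM on few counts, as Gm26497 did at 159 TPM from 17 counts in replicate 1. Length and low counts therefore cannot be told apart. The remaining 29 of the 79 rows are not accounted for by short length. Outside that set, at under 4-fold, Lars2 and Rpph1 were at 11523 and 4643 TPM and at 1302 and 4811 TPM in replicates 1 and 2, with effective lengths of 3721 and 162 bases.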
